A study of Homo sapiens with 9 samples.

How the data were processed

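RNA of human aortic endothelial cells was measured on 9 Illumina bead arrays, 3 per group (control siRNA, NOTCH1 siRNA and oxPAPC). Per the labels' protocols, cells were transfected with siPORT Amine or treated with oxPAPC at 50 µg/ml for 6 h in a low-serum medium, RNA was isolated on silica columns, and biotin-labelled cRNA was hybridised. The labels do not say whether the oxPAPC cells were also transfected, or how long the siRNA acted. Per the submitters' processing notes limma was used, with no version given. The deposited table holds log2 values per probe, a scale read from the values; the background correction, normalization and any filter on dim probes are not given in the sources used here. Every deposited array had a median of 7.77, and 75.8% of the sorted values differed by less than 0.01 between all arrays, so the values were used as deposited, with no further normalization. Such values measure change relative to the other genes of an array, and a shift of all genes would not be seen.

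The table held 20201 probes. The platform annotation gave 1 gene symbol for 15544 of them, several for 4 and none for 4653, and symbols were updated through Entrez identifiers, of which 15536 matched a RefSeq gene table that was used for names only. Probes with several symbols or none were left out of gene results, as were 21 probes of sex-linked genes. For 3120 genes with more than 1 probe, the probe with the highest mean over all arrays was used, which left 11565 genes. Probes of a gene passed the threshold in opposite directions for 14 genes with NOTCH1 siRNA and 57 with oxPAPC. Folds belong to the probe used, and other probes of some named genes passed in the same direction with another size, such as log2 differences with oxPAPC of 2.46 against 5.73 for GEM, -1.49 against -4.20 for PDGFB, 7.50 against 9.11 for HSPA6 and 4.32 against 3.48 for PTGS2. Of the 20 fixed genes, 17 were analysed here. The number of arrays limits the precision. No coordinates are given because the build behind the probes is not given in the sources used here.

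Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, all 3 groups in 1 fit that shares the estimate of spread), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Each NOTCH1 siRNA and oxPAPC group was compared with control siRNA and with each other. The 31 gene lists were tested with camera, which compares a list with the other genes, at an inter-gene correlation preset to 0.01 and again estimated from the data, and with fry, both with Benjamini-Hochberg adjustment over the lists. Counts adjusted over the list alone used the same p-values. Figures were drawn with matplotlib 3.10.9.

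The groups, the comparisons and their tests, the 31 lists, the alternatives and the rule for named genes were fixed before the data were examined. Centring on housekeeping genes, the gene groups added in the closing section and the tests of the interferon and NOTCH1 patterns were chosen after seeing the data. The rule named NOTCH1; per comparison with control, the 10 largest increases and the 10 largest decreases among genes past the threshold whose treated arrays all lay on one side of the controls, without provisional symbols; up to 4 members per list past the threshold, or 2 where none passed; the 10 genes changed most in both comparisons in the same direction and the 5 in opposite directions; and a fixed set of 20 genes including NOTCH1.

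The code was tested on simulated data with 200 of 11565 genes changed, 50 at each size. For the NOTCH1 siRNA comparison 14%, 44%, 84% and 96% of genes changed by 0.3, 0.6, 1 and 2 log2 units were recovered, with 5 false calls, and for the oxPAPC comparison 2%, 52%, 94% and 98%, with 6 false calls. In the data 30.5% and 50% of genes passed, which makes the adjustment less strict than in the simulation. These shares can therefore understate recovery there, where differences as small as 0.21 and 0.18 log2 units passed. Overlap between comparisons was set against 100 simulated data sets with unchanged groups, and the covariance was resampled over genes 1000 times. The alternatives were quantile normalization, centring on the array median or on housekeeping genes, filters on dim genes, other choices of probe, other variance estimates, array weights, fits of only the compared groups, other thresholds, the replicate number as a block, and leaving out each array in turn.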

Results

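Gene expression was measured in human aortic endothelial cells (HAEC), primary cells of the inner lining of the aorta, on Illumina bead arrays. There were 3 groups of 3 arrays: cells given a scrambled control siRNA, cells given an siRNA against the receptor NOTCH1, and cells given oxPAPC, an oxidised phospholipid mixture of the kind found in oxidised low-density lipoprotein, at 50 µg/ml for 6 h. The values were log2 probe values, and 11565 named genes were tested on the 9 arrays. The number of arrays limits the precision, with a median standard error of 0.117 log2 units for a difference between groups. The labels do not say whether replicates were separate cultures or donors, so p-values measure the spread between these arrays, which may be technical.

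Arrays of a group resembled each other more than arrays of other groups. Pearson's r across all deposited probes, which are not independent replicates, was 0.988 to 0.993 within groups and 0.937 to 0.98 between groups. The first principal component held 63.2% of the variance and set the oxPAPC arrays apart from the other groups, and the next held 17.1%.

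The knockdown comparison asked how the endothelial transcriptome differs when NOTCH1 is targeted. NOTCH1 itself was 10.12, 10.54 and 10.33 on the control arrays, 10.03, 9.94 and 9.76 on the NOTCH1 siRNA arrays, and 10.25, 10.12 and 9.80 on the oxPAPC arrays (log2, 1 probe). The log2 difference between NOTCH1 siRNA and control was -0.42 (SE 0.15, 95% interval -0.75 to -0.09, n = 3 and 3), and it did not pass limma's test (adjusted p = 0.0548), although all 3 siRNA arrays lay below all 3 controls. This call depended on the setting: the adjusted p ranged from 0.00635 to 0.168 over the alternatives tried, and it was 0.039, 0.0482 and 0.0356 without control replicate 1, oxPAPC replicate 1 and oxPAPC replicate 3.

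Transcriptional repressors downstream of Notch fell with NOTCH1 siRNA. HES4 fell 3.4-fold (log2 -1.77, SE 0.14), HEY2, an arterial regulator, fell 2.2-fold, HES1 fell 2.02-fold and HEY1 fell 1.47-fold (adjusted p 4.05e-05, 0.000117, 0.000269 and 0.0103). LFNG, a glycosyltransferase that modifies Notch receptors, rose 2.21-fold, and the ligands JAG2 and JAG1 rose 2.05-fold and 1.31-fold. NRARP, a feedback inhibitor of Notch, had a log2 difference of -0.16 (adjusted p = 0.594) and the receptor NOTCH4 one of 0.22 (adjusted p = 0.0908). The mean NRARP level over all arrays (5.27) lay close to the lowest value of an array (4.36 at the lowest), so a fall can be understated. Of 20 measured Notch receptors, ligands and direct targets, 3 rose, 7 fell and 10 did not pass, with 3 and 8 adjusted over the list alone. As a set this list did not stand apart from other genes in 1 direction (camera adjusted p = 0.221). Fry, which tests the list's own genes without comparing them with others, called it (adjusted p = 0.00723), as it did 20 of 31 lists. With the mean of all probes in place of the brightest, the LFNG call was lost (adjusted p = 0.0534), and dimmer probes of LFNG and HEY1 had log2 differences of 0.26 and -0.33 that did not pass (adjusted p = 0.578 and 0.235).

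**Figure D1:**
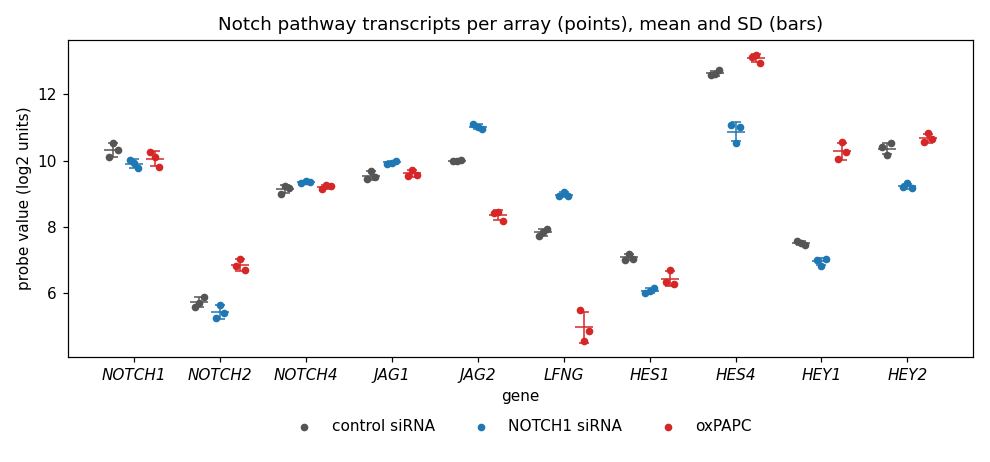
Probe values (log2 units) of Notch pathway genes on each of the 9 arrays, with points for arrays and bars for the mean and SD of each group of 3. HES1, HES4 and HEY2 lie lower on all NOTCH1 siRNA arrays than on all control arrays, and HEY1 and LFNG lie far apart between the siRNA and oxPAPC arrays.

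In all, 1741 genes rose and 1783 fell with NOTCH1 siRNA, 30.5% of those tested, and of these 171 rose and 292 fell by at least 2-fold. The balance depended on the scaling, as 49.4% of the called genes rose. With arrays centred on housekeeping genes, chosen after the data were seen, 52.6% of 3402 called genes rose. The values of the groups did not overlap for 48.5% of genes, where chance gives 10%. The largest increases were in PRND, a prion-like protein (16.2-fold, log2 4.01, SE 0.13), FNDC5, the irisin precursor (10.8-fold), TMEM178A (8.04-fold), PRDM1, a transcriptional repressor (6.41-fold), and LYVE1, a hyaluronan receptor of lymphatic endothelium (4.89-fold). MRAP2, an accessory protein of melanocortin receptors, CHRNA1, an acetylcholine receptor subunit, and CHST1, a sulfotransferase, rose 4.83-fold, 4.83-fold and 4.41-fold. The fatty acid binding protein FABP4 and the nuclear receptor PPARG rose 4.35-fold and 4.29-fold. The control levels of PRND (4.64), FNDC5 (4.88), CHRNA1 (4.93), TMEM178A (5.27) and PRDM1 (5.41) lay close to the lowest value of an array (4.36 at the lowest), so these folds can be understated and their order is not settled.

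The largest decrease with NOTCH1 siRNA was in the chemokine CCL5, which fell 49-fold, from 13.13 ± 0.05 to 7.52 ± 0.46 (log2, SD, n = 3; adjusted p = 8.15e-07). TNFSF13B, a B-cell survival cytokine, fell 16.2-fold, OASL, an antiviral protein, 15.7-fold, and CD38, an NAD-consuming ectoenzyme, 15.6-fold. The complement proteases C1S and C1R fell 15.2-fold and 11.4-fold, the phospholipase PLA1A 14.9-fold, the tryptophan-degrading enzyme IDO1 14.3-fold, the chemokine CXCL10 13.2-fold and LAMP3, a lysosomal membrane protein, 10.7-fold. On the siRNA arrays CD38 (5.07), C1S (5.22) and C1R (5.42) lay close to the lowest value of an array, so these folds can be understated. Of 3 C1R probes 1 dim probe had a log2 difference of 0.25 (adjusted p = 0.486), and the others fell.

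Interferon-stimulated genes fell almost throughout the list with NOTCH1 siRNA. Of 25 measured members 0 rose, 24 fell and 1 did not pass, and 24 fell adjusted over the list alone, with a mean log2 difference of -1.75. IFIT3 and RSAD2, which restrict viruses, fell 7.35-fold and 7.25-fold and MX2 fell 5.72-fold. The median over the list was 13.18 to 13.34 on the control arrays, 11.15 to 11.63 on the NOTCH1 siRNA arrays and 12.31 to 12.47 on the oxPAPC arrays. The list stood apart from other genes by camera with a preset correlation (adjusted p = 1.83e-16), and the call was lost at adjusted p = 0.339 with an estimated correlation.

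Metallothioneins, which bind metal ions, fell in all 6 measured members with NOTCH1 siRNA, also adjusted over the list alone (MT1M 6.63-fold, MT1G 2.58-fold, camera adjusted p = 4.69e-05). That call was lost at adjusted p = 0.269 with an estimated correlation. Of 10 replication-dependent histone genes 0 rose and 6 fell, the same counts adjusted over the list alone, with H2AC18 down 3-fold and H2BC21 down 2.78-fold (camera adjusted p = 0.00202, and adjusted p = 0.378 with an estimated correlation). Members of both families are near-identical in sequence, so values of single members are uncertain.

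In the list of cell cycle and DNA replication genes, most that passed rose with NOTCH1 siRNA. Of 30 measured 16 rose, 2 fell and 12 did not pass, with 17 and 2 adjusted over the list alone. The DNA replication genes were mixed. MCM7, TYMS and GINS2 rose, MCM3 and PCNA were the 2 that fell, and MCM2, MCM4, MCM5, MCM6, RRM2 and TK1 did not pass. CDC20 and UBE2C, which act in protein degradation at mitosis, rose 2.02-fold and 1.92-fold, and the mitotic kinesin KIF20A rose 1.82-fold. Of 27 cytosolic ribosomal protein genes 10 rose and 0 fell, also adjusted over the list alone, led by RPS23 at 2.29-fold and RPL22 at 1.59-fold. Both lists stood apart by camera (adjusted p = 0.000127 and 0.00202), and neither did at adjusted p = 0.279 and adjusted p = 0.212 with an estimated correlation. In all, camera called 5 of 31 lists with the preset correlation and 0 with the estimated one, where 5 had an unadjusted p under 0.05; limma's fry, which tests only whether a list's genes move on balance one way, called 20.

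Endothelial genes shifted in both directions with NOTCH1 siRNA, and none of these lists was called by camera. Of 19 pan-endothelial genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), among them the tight junction protein CLDN5 (2.71-fold), CD34 (2.39-fold), the receptor TIE1 (1.62-fold) and the nitric oxide synthase NOS3 (1.5-fold). Of 13 arterial identity genes 5 rose and 3 fell (7 and 3 adjusted over the list alone), with the gap junction protein GJA4 up 3.76-fold and the chemokine receptor CXCR4 up 2.95-fold. Of 7 venous and lymphatic genes 2 rose, LYVE1 and SELP, and 1 fell, the co-receptor NRP2 (2 and 2 adjusted over the list alone), and the mean of 0.16 and the median of -0.04 differed in sign. The NRP2 call rested on 1 of 3 probes, as the others had log2 differences of -0.20 and -0.23 (adjusted p = 0.342 and 0.361). SELP lost its call without control replicate 1 or 3 or siRNA replicate 2 (adjusted p = 0.0545, 0.0559 and 0.0548). Of 16 angiogenic tip cell and VEGF pathway genes 7 rose and 4 fell (8 and 4 adjusted over the list alone), led by the peptide hormone APLN (3.2-fold) and the growth factor PGF (2.65-fold). Of 13 junction and polarity genes 3 rose and 1 fell, the same adjusted over the list alone; GJA4, JAM2 (3.14-fold) and CLDN5 were those that rose.

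Adhesion and chemokine genes also split with NOTCH1 siRNA. SELE, the selectin that tethers leukocytes, rose 3.22-fold, while VCAM1, an adhesion molecule for monocytes, fell 1.95-fold; another, dimmer SELE probe had a log2 difference of 0.18 (adjusted p = 0.687), and all 3 VCAM1 probes fell. The chemokines CCL2 and CXCL1 rose 2.14-fold and 2.32-fold, and the chemokine CXCL12 rose 2.5-fold. The log2 differences of CXCL8, IL6 and ICAM1 were -0.02, -0.04 and 0.01, and none passed (adjusted p = 0.892, 0.813 and 0.98). Of 10 leukocyte adhesion molecules 4 rose and 1 fell, the same adjusted over the list alone. Of 21 chemokines and cytokines 6 rose and 4 fell (6 and 5 adjusted over the list alone), and the mean of -0.39 and the median of 0.01 differed in sign. Of 14 NF-kB targets 4 rose and 2 fell (5 and 2 adjusted over the list alone), with the superoxide dismutase SOD2 down 2.71-fold and the NF-kB inhibitor TNFAIP3 up 1.93-fold. None of these 3 lists was called by camera.

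Camera called none of the stress and metabolic lists for NOTCH1 siRNA. The stress transcription factor DDIT3 fell 1.95-fold and the haem-degrading enzyme HMOX1 rose 1.59-fold, while ATF3 had a log2 difference of -0.23 (adjusted p = 0.189). Counts of genes that rose and fell, the same adjusted over the list alone, were 2 and 4 of 24 unfolded protein response and ATF4 targets, 3 and 5 of 17 NRF2 targets, 2 and 1 of 14 heat shock genes, 6 and 0 of 20 cholesterol synthesis genes, 0 and 1 of 9 LXR targets, 0 and 2 of 16 immediate early genes and 4 and 5 of 18 hypoxia and glycolysis genes. Of these, the chaperone CRYAB fell 2.69-fold, the desaturase FADS1 rose 1.7-fold, the transcription factor KLF4 fell 1.73-fold and the glucose transporter SLC2A3 rose 2.3-fold. Of 15 cyclin-dependent kinase inhibitors and p53 targets 5 rose and 1 fell (7 and 1 adjusted over the list alone), of 18 TGF-beta and BMP response genes 2 rose and 7 fell, the same adjusted over the list alone, of 25 matrix genes 8 rose and 4 fell (8 and 5 adjusted over the list alone), and of 17 thrombosis and vasoregulation genes 2 rose and 4 fell (5 and 5 adjusted over the list alone). BMPER, a BMP modulator, fell 3.83-fold, the matrix protein POSTN rose 2.4-fold and the anticoagulant receptor THBD rose 2.49-fold. Of 17 respiratory chain genes only NDUFA9 passed, falling 1.37-fold, also adjusted over the list alone, and the list's direction was not settled, as its median of 0.02 and its mean just below 0 differed in sign.

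Markers of other cell types and control genes were examined beside these groups. With NOTCH1 siRNA, 3 of 4 measured smooth muscle markers rose and TAGLN, an actin-binding protein, fell 2.24-fold; 1 of 6 fibroblast markers rose, S100A4, by 2.89-fold; 0 of 4 leukocyte markers rose and CD68 and CD14 fell 4-fold and 1.48-fold. These counts were the same adjusted over the list alone. CD14 lost its call without control replicate 2 or 3 or siRNA replicate 1 or 3 (adjusted p = 0.086, 0.073, 0.0822 and 0.067). Of 6 epithelial markers MUC1 fell 1.79-fold (1 rose and 2 fell adjusted over the list alone). Dimmer probes of TAGLN and MUC1 had log2 differences of -0.41 and -0.71 that did not pass (adjusted p = 0.432 and 0.15). Of 12 housekeeping genes 1 rose, PPIA at 1.99-fold, and 3 fell, the same adjusted over the list alone. The PPIA probe was dim, with a mean level of 6.77 over all arrays, below the array median of 7.77. Camera called none of these 5 lists.

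The oxPAPC comparison asked which genes differ between oxPAPC-treated cells and control siRNA cells. No group given medium alone was measured. Effects of transfection, the control siRNA or the medium therefore cannot be told apart from those of oxPAPC. The largest increase was in the inducible chaperone HSPA6, which rose from 5.51 ± 0.44 to 14.62 ± 0.18 (log2, SD, n = 3; log2 difference 9.11, SE 0.20, adjusted p = 5.92e-09), and its close relative HSPA7 rose by 7.41 on the log2 scale. FOS, an immediate early transcription factor, rose 134-fold, GEM, a small GTPase, 53.1-fold, the chaperones HSPA1A and HSPA1B 42.4-fold and 34.7-fold and the co-chaperone DNAJB1 37.9-fold. HMOX1 rose 23.8-fold, TNFSF9, a costimulatory cytokine, 22.4-fold and the stress transcription factor ATF3 22.1-fold. HSPA1A and HSPA1B, like HSPA6 and HSPA7, are near-identical in sequence, so their probes may not tell them apart, and HSPA1A, HSPA1B and HMOX1 (15.35, 15.60 and 15.48 on the oxPAPC arrays) lay near the top of the scale, where folds can be understated. The control levels of FOS (4.66), GEM (4.72), HSPA7 (5.32) and HSPA6 (5.51) lay close to the lowest value of an array (4.36 at the lowest), so their folds can be understated and their order is not settled.

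The largest decreases with oxPAPC were in FAM43A (30.7-fold), FAM110D (21.6-fold), the serotonin receptor HTR2B (18.4-fold), the growth factor PDGFB (18.4-fold), the retinoic acid hydroxylase CYP26B1 (17.8-fold) and the growth factor BMP4 (15.5-fold). ZNF792, FAM124B, GIMAP8 and DEPP1 fell 14.8-fold, 13.9-fold, 13.1-fold and 11.6-fold. On the oxPAPC arrays BMP4 (4.70), ZNF792 (4.74) and FAM110D (5.55) lay close to the lowest value of an array, so their folds can be understated and their order is not settled. In all, 2338 genes rose and 3447 fell, 50% of those tested, and of these 607 rose and 790 fell by at least 2-fold. The groups did not overlap for 58.1% of genes, where chance gives 10%, and the median log2 difference of all genes was -0.08. The balance depended on the scaling: with arrays centred on housekeeping genes, chosen after the data were seen, 2699 genes rose and 2933 fell.

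Stress response lists rose with oxPAPC. All 14 heat shock genes rose (mean log2 difference 3.25), 15 of 16 immediate early genes rose, among them KLF4 (19.3-fold), NR4A2 (12.5-fold) and EGR1 (11.1-fold), and 14 of 17 NRF2 oxidative stress targets rose and 1 fell, among them SRXN1, which repairs peroxiredoxins (12.5-fold), and GCLM, of glutathione synthesis (5.83-fold). The control level of NR4A2 (5.39) lay close to the lowest value of an array, so its fold can be understated. The counts were the same adjusted over the list alone. Of 20 cholesterol biosynthesis and SREBP targets 17 rose and 0 fell (18 and 0 adjusted over the list alone), led by INSIG1, a sterol-sensing regulator (8.6-fold), the synthase HMGCS1 (6.59-fold) and the epoxidase SQLE (4.56-fold). These 4 lists were called by camera with the preset correlation (adjusted p = 3.43e-14, 1.35e-12, 1.08e-07 and 5.7e-10) and with the estimated one (adjusted p = 0.0141, 0.0141, 0.0204 and 0.0116 with an estimated correlation).

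Of 24 unfolded protein response and ATF4 targets 19 rose and 2 fell with oxPAPC (21 and 2 adjusted over the list alone), among them the chaperone DNAJB9 (8.18-fold), the stress sensor SESN2 (7.81-fold), PPP1R15A, which restores translation (5.13-fold), and DDIT3 (2.06-fold). Of 18 hypoxia and glycolysis genes 10 rose and 2 fell, the same adjusted over the list alone, with NDRG1 up 3.18-fold and VEGFA up 2.19-fold (a dimmer VEGFA probe had a log2 difference of 0.67, adjusted p = 0.116). Camera called both lists (adjusted p = 1.84e-09 and 9.97e-05), and both calls were lost at adjusted p = 0.105 and adjusted p = 0.0559 with an estimated correlation.

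Inflammatory genes split with oxPAPC. The neutrophil chemokine CXCL8 rose 4.67-fold, CXCL2 4.31-fold, CXCL1 3.5-fold and the cytokine IL11 5.48-fold, IL6 rose 1.32-fold, and the monocyte chemokine CCL2 fell 2.94-fold. CXCL8 on the oxPAPC arrays (15.64) lay near the top of the scale, so its fold can be understated, and its other probe rose by 3.13 on the log2 scale. The control level of IL11 (4.88) lay close to the lowest value of an array, so its fold can be understated. VCAM1 fell 3.87-fold and SELE 1.62-fold, and ICAM1 had a log2 difference of 0.39 (adjusted p = 0.103); the dimmer SELE probe had one of -0.42 (adjusted p = 0.264). Of 21 chemokines and cytokines 9 rose and 4 fell (10 and 4 adjusted over the list alone), and of 14 NF-kB targets 8 rose and 3 fell (9 and 3 adjusted over the list alone), including the prostaglandin synthase PTGS2 (11.1-fold up) and the coactivator BCL3 (5.29-fold down). Camera called both (adjusted p = 0.0311 and 0.0298), and the calls were lost at adjusted p = 0.245 and adjusted p = 0.251 with an estimated correlation, at 0.0533 for the chemokines without control replicate 2 and at 0.0575 for the NF-kB targets without oxPAPC replicate 1. Of 10 leukocyte adhesion molecules 1 rose and 4 fell, the same adjusted over the list alone, and camera did not call them. JAM3 was the one that rose (1.35-fold), and its call was lost without control replicate 2 or 3 or oxPAPC replicate 2 or 3 (adjusted p = 0.0779, 0.0819, 0.0752 and 0.0835).

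**Figure D2:**
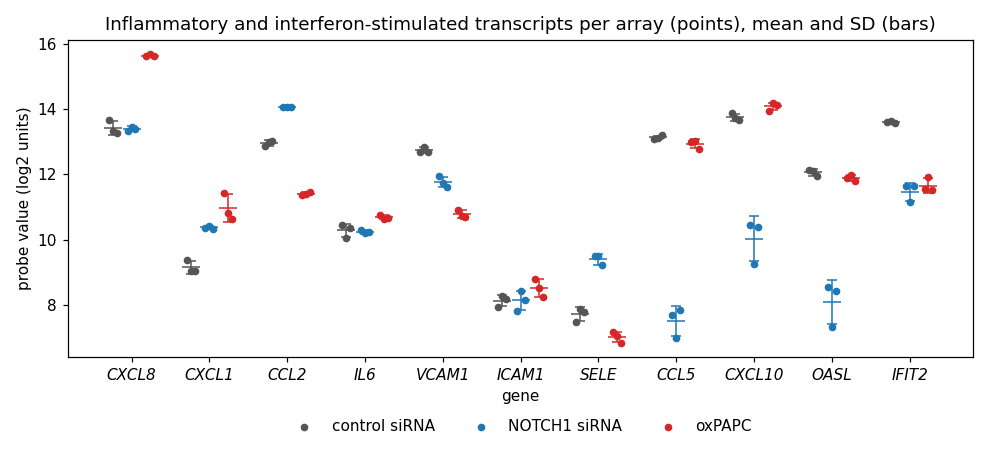
Probe values (log2 units) of inflammatory and interferon-stimulated genes on each of the 9 arrays, with points for arrays and bars for the mean and SD of each group of 3. CCL5, CXCL10 and OASL are low on the NOTCH1 siRNA arrays and near the control level on the oxPAPC arrays, while CXCL8 is highest on the oxPAPC arrays.

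Of the 25 interferon-stimulated genes 0 rose and 10 fell with oxPAPC, and 7 fell adjusted over the list alone. IFIT2 fell 3.84-fold, IFIT3 2.65-fold and the RNA sensor RIGI 2.26-fold, while OASL and CXCL10 had log2 differences of -0.18 and 0.32 that did not pass (adjusted p = 0.613 and 0.362). Camera called the list (adjusted p = 0.0478), and the call was lost at adjusted p = 0.802 with an estimated correlation, without control replicate 1, 2 or 3 (adjusted p = 0.0848, 0.0541 and 0.0526) and without oxPAPC replicate 1 or 3 (adjusted p = 0.0887 and 0.0725).

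Proliferation and endothelial genes fell with oxPAPC. Of 30 cell cycle genes 0 rose and 20 fell, the topoisomerase TOP2A by 3.37-fold and the kinase AURKA by 2.78-fold, and of 19 pan-endothelial genes 0 rose and 14 fell, the sphingosine phosphate receptor S1PR1 by 2.39-fold and TIE1 by 1.9-fold. Of 6 metallothioneins 0 rose and 5 fell, led by MT1F at 4.09-fold. The counts were the same adjusted over the list alone. Camera called these 3 lists (adjusted p = 1.28e-05, 0.00252 and 0.0115), and the calls were lost at adjusted p = 0.116, adjusted p = 0.116 and adjusted p = 0.245 with an estimated correlation. Of 31 lists, camera called 12 with the preset correlation and 4 with the estimated one, and fry called 25.

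Notch genes moved apart with oxPAPC. HEY1 rose 6.86-fold and the receptor NOTCH2 2.18-fold, while LFNG fell 7.32-fold, JAG2 3.13-fold and HES1 1.56-fold. A dimmer LFNG probe had a log2 difference of 0.12 (adjusted p = 0.767), and on the oxPAPC arrays LFNG (4.96) and NRARP (4.92) lay close to the lowest value of an array. NOTCH1 had a log2 difference of -0.28 (95% interval -0.61 to 0.05, adjusted p = 0.145), JAG1 one of 0.07 (adjusted p = 0.578) and NOTCH4 one of 0.08 (adjusted p = 0.495). HEY2 rose 1.24-fold and NRARP fell 1.53-fold (adjusted p = 0.0413 and 0.0278). Both calls depended on single arrays: HEY2 had 0.072 without control replicate 1, 0.134 without control replicate 2, 0.0586, 0.0516 and 0.0541 without siRNA replicates 1, 2 and 3, and 0.125 and 0.0773 without oxPAPC replicates 2 and 3, and NRARP had 0.0966 without control replicate 3 and 0.0904 without oxPAPC replicate 2. Of the 20 listed Notch genes 5 rose and 7 fell (5 and 8 adjusted over the list alone), and camera did not call the list (adjusted p = 0.754).

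Other vascular lists held members with large changes in both directions, and camera called none of them for oxPAPC. Rises and falls, the same adjusted over the list alone, numbered 4 and 7 of 13 arterial identity genes, with CXCR4 down 8.56-fold and GJA4 down 3.47-fold; 1 and 2 of 7 venous and lymphatic genes, with RELN up 7.55-fold and NRP2 down 6.51-fold on 1 of 3 probes (the others -0.14 and -0.36 in log2, adjusted p = 0.442 and 0.115); and 4 and 7 of 16 angiogenic genes, with APLN down 2.55-fold. On the oxPAPC arrays CXCR4 (5.35) and NRP2 (5.33) lay close to the lowest value of an array, so their folds can be understated. Rises and falls numbered 4 and 6 of 17 thrombosis and vasoregulation genes, with tissue factor, F3, up 13.2-fold and the vasoconstrictor EDN1 down 7.36-fold, and 3 and 5 of 13 junction genes, with GJA1 up 2.48-fold. They numbered 3 and 8 of 18 TGF-beta and BMP genes, with BMP2 up 6.74-fold and ID1 down 4.88-fold, 3 and 5 of 9 LXR targets, with the cholesterol transporter ABCA1 down 3.06-fold, and 3 and 6 of 15 cyclin-dependent kinase inhibitors and p53 targets, with SESN1 down 3.7-fold. Of 25 matrix genes 7 rose and 1 fell (6 and 1 adjusted over the list alone), with the protease ADAMTS1 up 16.1-fold. The mean and median differed in sign for the angiogenic genes (-0.50 and 0.10) and the thrombosis genes (0.17 and -0.05).

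Of 17 respiratory chain genes 1 rose and 6 fell (1 and 5 adjusted over the list alone), and of 10 replication-dependent histone genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), H4C8 by 4.16-fold. Of 27 ribosomal protein genes 0 passed in limma's test, and their mean of -0.01 became 0.05 when arrays were centred on housekeeping genes, a setting chosen after the data were seen. Of 12 housekeeping genes 1 rose and 2 fell, with TUBB down 1.61-fold (another probe -0.20 in log2, adjusted p = 0.193). Of 4 smooth muscle markers SMTN rose 2.5-fold and ACTA2 fell 1.23-fold, and 0 of 6 fibroblast, 0 of 4 leukocyte and 0 of 6 epithelial markers passed. Camera called none of these 8 lists. For the 6 from ribosomal to epithelial the counts were the same adjusted over the list alone; the mean and the direction of the test differed in sign for the housekeeping and ribosomal lists, and the mean and median for the epithelial markers (0.05 and -0.01).

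**Figure D3:**
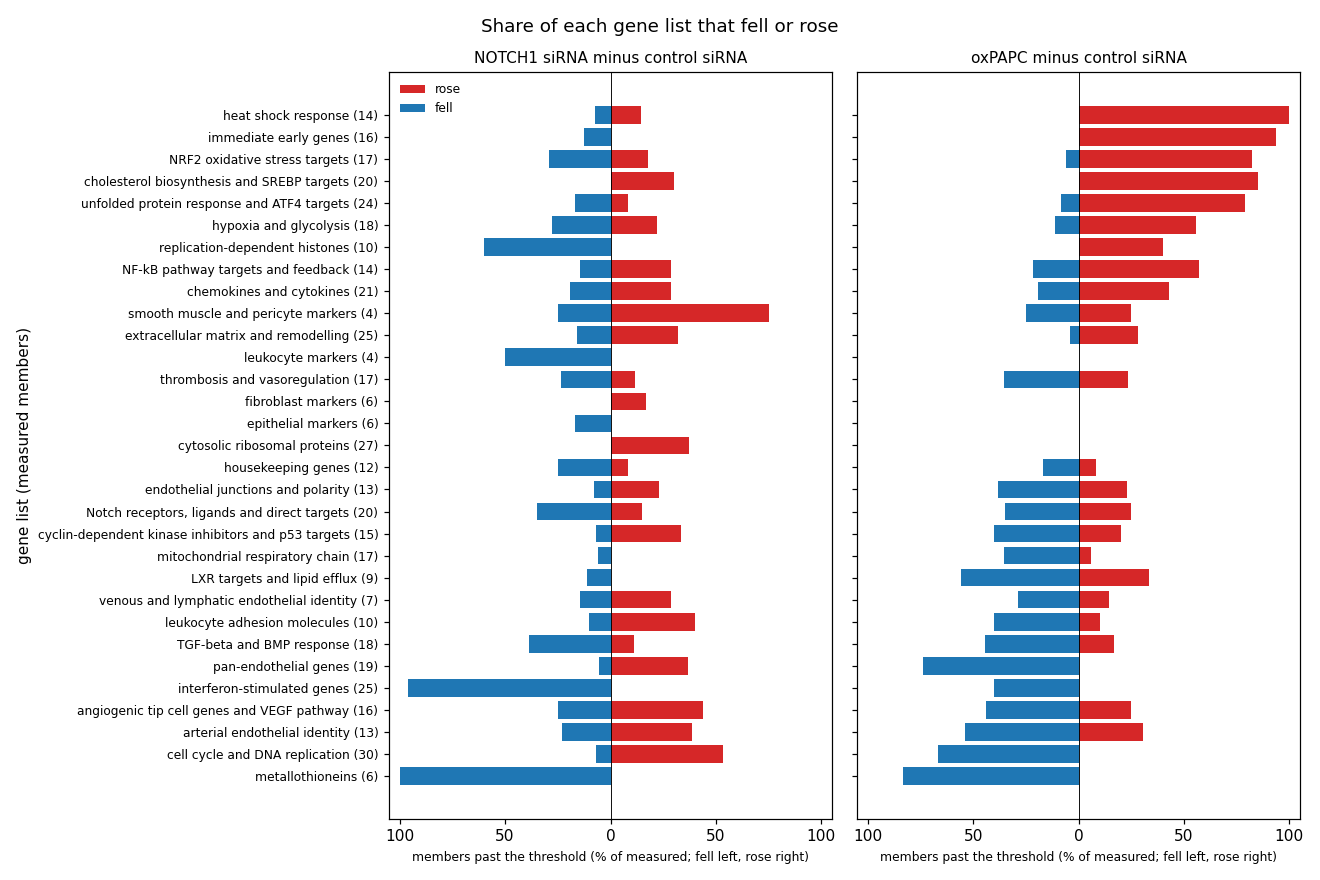
Share of the measured members of each of the 31 gene lists that fell (left) or rose (right), in percent, for NOTCH1 siRNA and oxPAPC against control; the number of measured members stands beside each name. Nearly all interferon-stimulated genes fell with NOTCH1 siRNA (24 of 25), and all 14 heat shock genes rose with oxPAPC.

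NOTCH1 siRNA and oxPAPC were compared directly as well. Here 3875 genes were higher and 2911 lower with NOTCH1 siRNA than with oxPAPC, 58.7% of those tested, 1058 and 962 of them by at least 2-fold. Cell cycle genes (25 of 30) and pan-endothelial genes (14 of 19) were higher with NOTCH1 siRNA, with 0 lower in either list. All 14 heat shock genes, 15 of 16 immediate early genes, 22 of 25 interferon-stimulated genes, 14 of 18 hypoxia genes and 8 of 10 histone genes were lower, with 0 higher. The unfolded protein response (20 of 24 lower), NRF2 (13 of 17), cholesterol (15 of 20) and chemokine (13 of 21) lists were lower with 2, 1, 2 and 3 members higher. Adjusted over the list alone the counts were the same except for 26 cell cycle genes higher, 15 pan-endothelial genes higher and 1 lower, 15 NRF2 targets lower and 14 chemokines lower. Camera called these 11 lists, and the heat shock, immediate early, cholesterol and NRF2 lists kept their calls (adjusted p = 0.0263, 0.0263, 0.0263 and 0.0357 with an estimated correlation). The other adjusted p-values with an estimated correlation were 0.0663 for the cell cycle, 0.0923 for pan-endothelial, 0.396 for interferon, 0.0663 for hypoxia, 0.196 for histone, 0.112 for unfolded protein response and 0.169 for chemokine genes. CCL5 was lower by a log2 difference of -5.42 and CXCL10 by one of -4.05, and LFNG was higher by 4.02.

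Genes that changed in both comparisons with the control went together about as often as apart. Of 1973 such genes 373 were higher and 643 lower in both, while 554 rose with NOTCH1 siRNA and fell with oxPAPC and 403 did the reverse. Independent lists of these sizes would share 352, 531.4, 518.9 and 360.5 genes. Among the same-direction genes, the iron exporter SLC40A1 (log2 -2.60 with siRNA), IFIT2, IFIT3, RTP4, PARP9, UBD, RNF213 and CCNJ fell and PPARG and SIPA1L2 rose. Opposite changes were seen for the transcription factor MYCN (log2 2.07 and -2.59), FABP4 (2.12 and -2.04), GJA4 (1.91 and -1.79), the G-protein regulator RGS2 (-1.76 and 2.98) and the arrestin ARRB1 (1.63 and -1.68). With NOTCH1 siRNA the ARRB1 call rested on 1 of 3 probes (the others 0.11 and 0.04, adjusted p = 0.624 and 0.867), and with oxPAPC the MYCN call rested on 1 of 2 (the other -0.05, adjusted p = 0.873), where its level of 5.16 lay close to the lowest value of an array. A dimmer RNF213 probe had -0.40 with NOTCH1 siRNA (adjusted p = 0.113). Of the cell cycle genes 13 rose with NOTCH1 siRNA and fell with oxPAPC.

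Both comparisons shared the control arrays, which alone ties their values. In 100 simulated data sets without effects, r across genes was 0.5 and the covariance 0.0143 on average, against an observed r of 0.033, Spearman's rho of 0.064 (0.459 simulated) and covariance of 0.0113 (bootstrap interval over genes 0.0049 to 0.0181). Without effects, the shared controls alone set r near 0.5. Real changes widen the fold changes (SD over genes 0.473 with NOTCH1 siRNA and 0.728 with oxPAPC, median SE 0.117), which lowers r. The simulated r and rho are therefore no baseline for the observed ones, and only the covariance can be compared. Genes are not independent replicates, and the observed covariance lay below the simulated one by 0.003, within the bootstrap interval. The simulation used 1 spread per gene pooled over the 3 groups, while only the control arrays are shared. The median SD within groups was 0.121 for control, 0.112 for NOTCH1 siRNA and 0.142 for oxPAPC. The difference of 0.003 may therefore come from this setting. Without control replicates 1, 2 and 3 the covariance was 0.0191, 0.0157 and 0.0167, in fits with fewer controls, where shared controls alone give a larger covariance than the simulated one. The 3 controls were not split between the comparisons, as a split leaves 1 comparison with 1 control array. Part of any shared calls may therefore come from the shared controls.

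**Figure D4:**
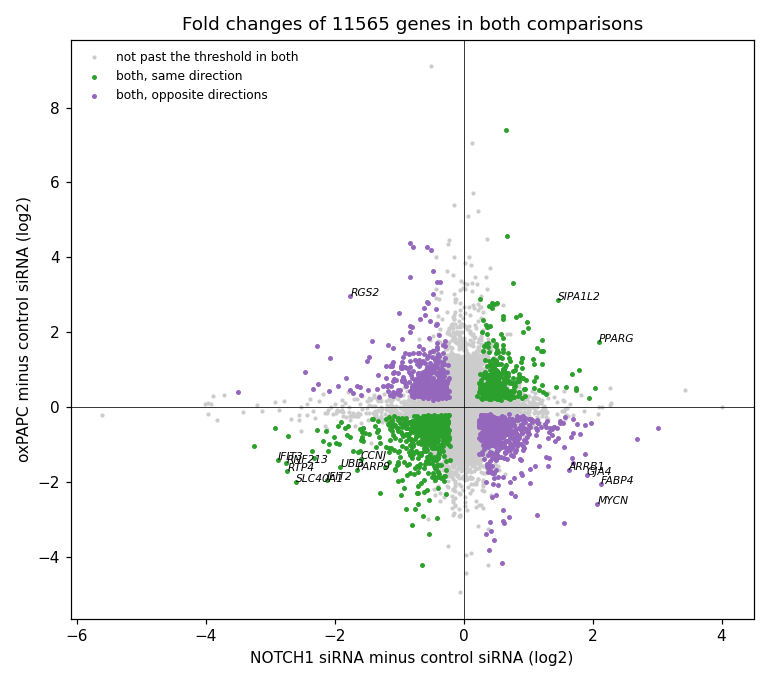
Log2 difference from control for NOTCH1 siRNA (horizontal) and oxPAPC (vertical) of 11565 genes, with a point per gene; green points passed in both with the same direction, purple points in both with opposite directions, and labels mark the genes named for the overlap. Of the 1973 genes that passed in both, 48.5% had opposite directions.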

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

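Among the alternatives, only centring on housekeeping genes was chosen after seeing the data. All counts of genes past the threshold kept within 1.5 times of the reported count except under stricter thresholds or with fewer genes tested, where the construction explains the fall. With NOTCH1 siRNA, an adjusted p under 0.01 gave 926 higher and 1059 lower, and at least 1.5-fold gave 651 and 827. With oxPAPC, genes above the median level gave 1455 and 2242, and at least 1.5-fold 1367 and 1931. For NOTCH1 siRNA minus oxPAPC these were 2394 and 1770, and 2381 and 1895. Genes called in both at an adjusted p under 0.01 numbered 426 in the same and 412 in opposite directions. Without single arrays, genes higher and lower ranged from 1258 to 1808 and 1373 to 1841 with NOTCH1 siRNA, 2010 to 2296 and 3047 to 3380 with oxPAPC, and 3509 to 3838 and 2664 to 2901 for the direct comparison. At least 72.3% of the reported genes with NOTCH1 siRNA and 85.3% with oxPAPC were shared, in the same direction. Median centring moved no count, and quantile normalization kept 99.5% and 98.9% of calls.

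The NOTCH1 log2 difference with siRNA stayed negative, and its adjusted p of 0.0548 crossed the threshold under several settings: -0.42 with genes above the median level (0.0117), with the dimmest 25% left out (0.025), with trend and robust eBayes (0.00635) and with only the compared groups (0.0422), and -0.41 with array weights (0.032). Without single arrays it ranged from -0.53 to -0.32 (0.0356 to 0.168). With oxPAPC, trend and robust eBayes gave -0.28 (0.0492), and the adjusted p otherwise ranged from 0.0643 to 0.419. The cause was not tested.

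Camera with an estimated correlation called 0, 4 and 4 lists for NOTCH1 siRNA, oxPAPC and the direct comparison (5, 8 and 9 at an unadjusted p under 0.05), against 5, 12 and 11 with the preset one, and fry, which asks another question, called 20, 25 and 27. With genes above the median level, the oxPAPC calls of the chemokine (adjusted p = 0.138), NF-kB (0.284), interferon (0.095) and metallothionein (0.141) lists were lost. Values with another sign came from other probes of a gene: with the most variable probe LSS was -0.23, BAX -0.023 and SDHA 0.39 with NOTCH1 siRNA, and BAX 0.92 and NECTIN2 -0.21 with oxPAPC, where the mean of probes gave BAX 0.43. Under fry the housekeeping list, with a mean of -0.065, pointed down with oxPAPC, and the cause was not tested. The covariance between comparisons was 0.005 with genes above the median level and ranged from 0.0095 to 0.0191 without single arrays.

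The replicate numbers do not pair the arrays: deviations from group means correlated at -0.102 to 0.045 between arrays of the same number and at -0.077 to 0.067 between others, and 3 of 9 arrays correlated best with their own number. With the replicate block, 1528 genes were higher and 1564 lower with NOTCH1 siRNA, 2245 and 3303 with oxPAPC, and 3756 and 2825 in the direct comparison. The log2(value + 16) alternative was not run because the values were already logarithmic, and NOTCH1 had 1 probe, so no other probe of it was tried.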

Other observations

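The added gene groups (antigen presentation, proteasome, GIMAP, DNAJ, ZNF and aminoacyl-tRNA synthetases), their tests and the tests of the interferon and NOTCH1 patterns were chosen after the results were seen. The splits of the arrays were planned. Camera p-values of the added groups were adjusted over these groups alone. They describe values already seen and are not tests of a question set beforehand.

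Antigen presentation genes fell with NOTCH1 siRNA: of 17 measured 0 rose and 16 fell (mean log2 difference -1.04), among them the immunoproteasome subunit PSMB9 (-2.30), the peptide transporter TAP2 (-1.61) and HLA-C (-1.42). Camera gave an adjusted p of 3.47e-11, and adjusted p = 0.104 with an estimated correlation. Of 30 other 20S and 26S proteasome subunits 12 fell and 1 rose, led by PSMA6 (-0.71). Their camera adjusted p was 0.00238, and adjusted p = 0.0531 with an estimated correlation. PSMB5, PSMB6 and PSMB7 (0.02, -0.09 and -0.21) did not pass limma's test (adjusted p = 0.873, 0.431 and 0.0858). With oxPAPC 0 antigen presentation genes rose and 4 fell, and 9 proteasome subunits rose and 5 fell, PSMD3 by 1.04 upward; camera called neither list (adjusted p = 0.491 and 0.182).

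With oxPAPC all 7 GIMAP genes, which encode immune-associated GTPases, fell (mean log2 difference -2.11; GIMAP8 -3.71 and GIMAP7 -3.37; camera adjusted p = 0.00011, and adjusted p = 0.0603 with an estimated correlation). Of 37 DNAJ co-chaperones 14 rose and 10 fell, with DNAJA4 at 4.35 beside DNAJB1. Of 312 ZNF-named zinc finger genes 56 rose and 126 fell (camera adjusted p = 0.0767). Of 18 aminoacyl-tRNA synthetases 1 rose and 7 fell with NOTCH1 siRNA, WARS1 by -1.21, at adjusted p = 0.0427 and adjusted p = 0.219 with an estimated correlation. Among 4657 probes with no single gene name, 495 were higher and 283 lower with NOTCH1 siRNA and 747 and 562 with oxPAPC.

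The interferon-stimulated genes lay lower on the NOTCH1 siRNA arrays than on the control arrays. Single arrays do not account for this, since the lowest control median over the list exceeded the highest siRNA median by 1.55, against a widest range within a group of 0.48. A rise with the control siRNA was taken as the only cause, with no siRNA in the oxPAPC cells and no rise from oxPAPC. The oxPAPC arrays would then lie no higher than the NOTCH1 siRNA arrays, but the median over the list was 1.07 higher (bootstrap SE 0.24). A rise with the control siRNA joined by a fall with the NOTCH1 siRNA also allows oxPAPC arrays between the groups, so it stays open. It also stays open whether the control siRNA raised these genes in both of the other groups. The oxPAPC arrays lay between the other groups, below the controls by a median over genes of -0.33 (SE 0.14). Neither a response to the control siRNA nor an effect of NOTCH1 loss sets where they should lie. Both SEs come from resampling the list's genes, which moved together (estimated correlation 0.807), and do not measure the spread between arrays. With 1 siRNA against 1 control, an effect of NOTCH1 loss cannot be told apart from any other effect of either siRNA. No second NOTCH1 siRNA was measured. Loss of NOTCH1 may be the biological source, as a hypothesis that these data do not settle.

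The NOTCH1 transcript differed little on the NOTCH1 siRNA arrays although HES1, HES4 and HEY2 fell. An exchange of 1 array with another group is argued against by correlations, since the lowest r among the siRNA arrays exceeded their highest r with any other array by 0.012. A probe at background or at the top of the scale is argued against by its level, at percentile 73 of the genes tested. A knockdown seen more in protein than in transcript, a probe that reads a part of the transcript left after cleavage, and a weak knockdown may each apply, and none was tested.

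The count of genes past the threshold was compared with other splits of the same arrays. For each comparison 1 of 10 splits gave as many genes, the real one, with 3524, 5785 and 6786 genes by limma against a highest other count of 0 (351, 432 and 306 genes at an unadjusted p under 0.05). The splits are too few for a share under 0.05. Every other split mixes arrays of both groups, which puts the group difference into the spread. Its count is therefore no baseline for arrays without a difference.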
